A study of Mus musculus with 9 samples.

How the data were processed

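RNA from the whole tongue of mice about 6 weeks old, on a C57/Bl6 and FVB/NJ mixed background, was measured by RNA sequencing in 9 libraries. Every mouse drank doxycycline at 2 mg/mL for 1 week. The control group held 5 libraries from mice carrying K14-rtTA alone, in which the keratin 14 promoter drives a doxycycline-dependent transcription activator in basal epithelial cells. The Bmi1 transgene group held 4 libraries from mice that also carried TREFLBmi-1, the inducible Bmi1 transgene. Bmi1 is a subunit of Polycomb repressive complex 1. The labels do not say that each library came from its own animal, so p-values measure the spread between these libraries. That spread is the deposited one, of which a part is absent, as described below. Replicates were numbered in accession order within a group, and the numbers pair no libraries between groups.

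Per the labels' protocols, stranded mRNA libraries were read from 1 end on a HiSeq4000. Per the submitters' processing notes, the tools were TopHat2, HTSeq and DESeq2 and the genome build was mm9, with versions and settings not given in the sources used here. The authors deposited log2 normalized expression values for 20512 gene symbols and no read counts, so the depth of each library is unknown. The deposited log2 values ran from -3.31 to 18.91, and the values taken back to the linear scale had nearly equal sums over the libraries. Low genes such as Cdkn2a (-0.56 to -0.54) were nearly equal across libraries, as in a regularized log, so fold changes of low genes may be understated. The size of such an effect was not measured. A set of 3064 genes stood at exactly 0 in every library and was left out; it included all 8 globin genes of the table, and nothing is said here about their expression. One row without a gene name was left out as well.

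The authors also deposited a table of their own comparison with 981 genes. Per the file headers it holds a mean normalized signal per gene, a log2 fold change with its standard error, the linear ratio of the groups, a test score and a p-value with its adjusted form. The test score equals the authors' log2 fold change divided by its standard error, and the largest adjusted p-value in the table is 0.0498. The authors' values are quoted as theirs and have no replicate spread of their own here.

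The deposited log2 values have the form left by a correction that no label names. Libraries within 2 groups of 5 and 4 can vary in 7 directions, and only 5 directions held any variation. A search over splits of the 9 libraries found 1 partition into 3 sets, of 3003 tried, whose set means left no effect in any gene once the group means were allowed for. None of 7634 partitions into 4 sets did so. The 3 sets are called strata below. Stratum 1 holds control replicate 1 and transgene replicate 1, stratum 2 holds control replicates 2 and 3 and transgene replicates 2, 3 and 4, and stratum 3 holds control replicates 4 and 5. No gene thus holds a difference between strata beyond what the group means account for. An additive correction per stratum that spares the group means would leave such values, but values from before any correction were not analysed here, so whether the group means are those before it is unknown. What the strata stand for (a sequencing run, sex, a litter or something else) is not given in the sources used here. Least squares with terms for the strata gives the same log2 difference as the group means. In that estimate stratum 1 carries 29.4% of the weight and stratum 2 carries 70.6%, while stratum 3 carries none because it holds no transgene library.

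Genes with a mean log2 value of at least 3 were tested, which left 14490 genes. The test fixed before the data were examined was limma 3.58.1 in R 4.3.3 on the log2 values with the group as the only term, an intensity trend in the variance prior, two-sided p-values and Benjamini-Hochberg adjustment, with genes called at an adjusted p under 0.05. It is called the group-only fit below, and it counts 7 residual degrees of freedom although 5 exist. On simulated data with the same strata removed from 14490 genes, the group-only fit put 14.2% of unchanged genes under an unadjusted p of 0.05 and made 169 false calls beside 200 changed genes. The fit with stratum terms put 5.1% there and made 9 false calls, and it recovered 91% of genes changed by 0.5 and 99% of genes changed by 1 on the log2 scale. Numbers of calls in the fit with stratum terms are therefore given beside those of the group-only fit. That fit was added after the data were seen. The simulated errors were independent between genes and equal in both groups, with no length trend, so these rates need not hold for the real values.

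Gene lists for cell types and processes were fixed before the data were examined and tested with camera in limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 38 lists that had at least 5 tested members. Members are also counted with adjustment over the list alone. A list score is the mean log2 value over the tested members in a library, and scores and single genes were compared with a two-sided exact permutation test over the 126 splits of the 9 libraries into 5 and 4. The smallest p this test can give is 0.00794. Since the values hold no other differences between strata, this test favours the real split. Within strata there are 20 such splits, and the smallest p is 0.05, so no test within strata can fall under that limit. That test too takes the plain difference of group means. The stratum means follow the real groups, so its splits are not balanced around no difference and its p-values need not be exact. The lists for Hox genes, for B and plasma cells and for red blood cells had too few tested members and were not tested.

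Genes are named by a rule fixed before the data were examined. It takes Bmi1, Cdkn2a and Cdkn2b, the 12 largest rises and 12 largest falls among called genes with a standard symbol, up to 4 members with the smallest p of each list past the test, up to 2 members with the highest mean of any other list described with members, and the 5 largest and 5 smallest fold changes in the authors' deposited table. Genes named outside the rule are said to be so. Keratin-associated protein genes form a family of close copies, and the split of reads between them is uncertain.

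Transcript lengths came from GENCODE M21 and were found for 99.4% of tested genes, of which 13702 matched by current and 701 by older symbol. Each library's trend on log2 length was removed with a spline of 4 degrees of freedom as an added alternative. No coordinates are given, because the authors' build differs from that annotation. The other alternatives were no filter, a floor of 5, quantile normalization, median centring, 8 added on the linear scale, other variance priors, library weights, a muscle to keratinocyte covariate, each library left out, stratum 2 alone, a covariate from Y-linked genes, and for lists an estimated correlation, ranks and fry. Fits and list tests with 1 library left out had the group as the only term, so their p-values share the limits of the group-only fit. No library repeated another: the SD of log2 differences over genes was 0.0836 for the closest pair, control replicates 3 and 4. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining steps.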

Results

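Whole-tongue RNA was compared between 5 control mice libraries (K14-rtTA alone) and 4 Bmi1 transgene libraries (K14-rtTA with TREFLBmi-1), all after 1 week of doxycycline. The comparison asks which transcripts differ in the tongue when Bmi1 is induced in keratin 14-expressing epithelium. Values are deposited log2 normalized expression, so a difference of 1 is a doubling, and the read depth behind each library is unknown. Every difference is transgene minus control.

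Bmi1 itself was higher in the transgene group by 2.44 on the log2 scale (SE 0.49 in the group-only fit), a 5.43-fold difference. The mean was 10.40 ± 0.21 (SD, n = 5) in controls and 12.84 ± 1.37 (SD, n = 4) in transgene libraries. All 4 transgene libraries lay above all 5 controls, whose highest value was 10.74. The transgene libraries were uneven, at 12.49, 12.05, 14.87 and 11.94 for replicates 1 to 4. The adjusted p was 0.00719 in the group-only fit of limma and 0.0672 with stratum terms, where the SE was 0.60. The exact permutation test gave p = 0.00794, the smallest that 126 splits allow, and p = 0.05 within strata, the smallest that 20 splits allow. Bmi1 was higher in both strata that hold the 2 groups, by 1.76 in stratum 1 and 2.73 in stratum 2. Transgene replicate 3 set much of the size: without it the difference was 1.77 (adjusted p 0.000907 in the group-only fit). That setting was not run with stratum terms. Whether these values hold transgene or endogenous Bmi1 transcripts was not separated. Bmi1 is not among the 981 genes of the authors' deposited table.

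Cdkn2a, the Ink4a/Arf locus that Bmi1 represses in many cell types, stood between -0.56 and -0.54 in every library, below the floor for testing, so a lower level could not have been detected. Its difference was 0.00 (exact permutation p = 0.484, and 0.45 within strata). Its neighbour Cdkn2b, which encodes p15, fell by 0.41 (SE 0.08), with an adjusted p of 0.00511 in the group-only fit and 0.0617 with stratum terms. All 4 transgene libraries lay below all 5 controls for Cdkn2b, with a difference of -0.37 in stratum 1 and -0.43 in stratum 2. Such full separation of the groups is common in these values and sets no gene apart: it holds for 3092 of 14490 tested genes (21.3%).

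**Figure D1:**
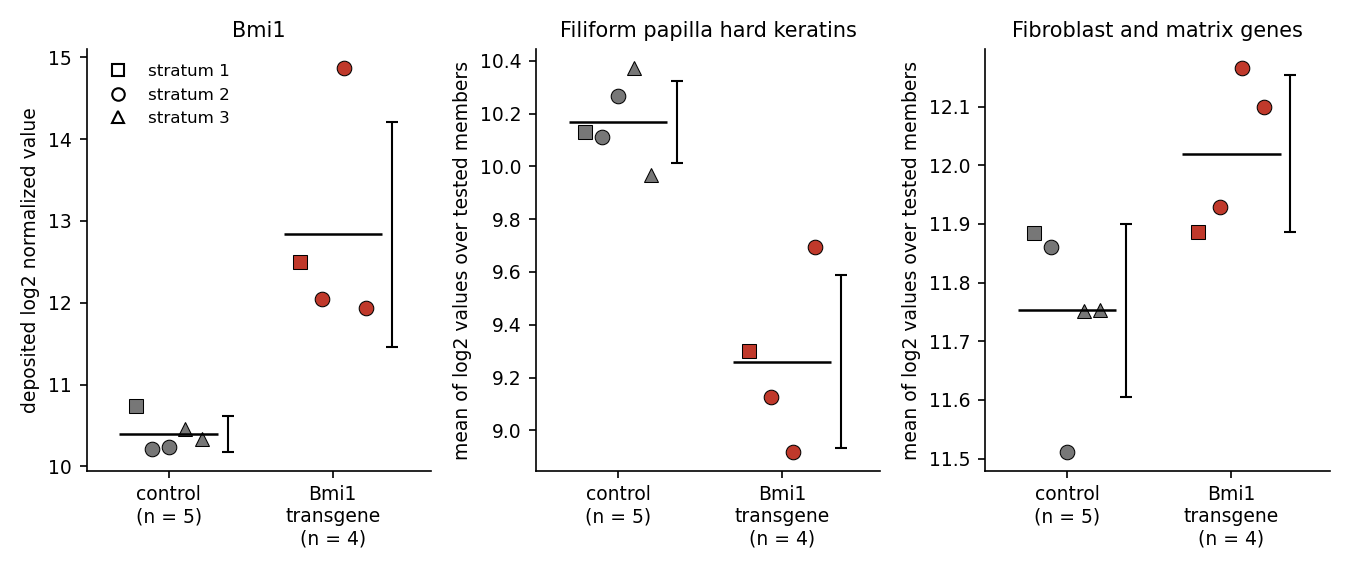
Deposited log2 value of Bmi1 (left) and mean log2 value over the tested members of the filiform papilla hard keratin list (middle) and of the fibroblast and matrix list (right), with 1 point per library, shaped by stratum. Horizontal lines are group means and bars are ± 1 SD; hard keratin scores lie between 9.97 and 10.37 in the 5 controls and between 8.92 and 9.69 in the 4 transgene libraries, and the y axes do not start at 0.

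In the deposited log2 values, the structural genes of the filiform papillae, the horny spines of the tongue surface, were about halved in transgene tongues. The authors' own fold changes are smaller for some of these genes, as given below. Of 19 tested members of the hard keratin list, 17 fell in the group-only fit (17 when adjusted over the list alone) and 10 fell with stratum terms (17 when adjusted over the list alone). With stratum terms and the length trend taken out, limma called 0, against 16 lower at an unadjusted p under 0.05. The median difference over the list was -1.01 in all 9 libraries. Krtap3-1, a keratin-associated protein that binds hard keratin filaments, changed by -1.25 (SE 0.18 with stratum terms, adjusted p 0.0407), and Krtap3-3 changed by -1.13 (SE 0.13, adjusted p 0.0221). The type I hard keratin Krt31 changed by -1.10 (adjusted p 0.0418) and the type II hard keratin Krt85 by -1.08 (adjusted p 0.0407) in the same fit. Krt36 (-0.86, adjusted p 0.0475) and Krt84 (-0.78, adjusted p 0.0694), with higher levels than Krt31 and Krt85, fell less and are named outside the rule. Krt84 was at 13.26 in transgene replicate 4 and at 13.21 in control replicate 2, so its groups overlap. The members that did not pass in the group-only fit were Krt23 at -0.10 and Krt75 at -0.19, named here after their values were seen. With stratum terms Krt33a, Krt35, Krt83, Krt84, Krt86, Krtap3-2 and Hoxc13 did not pass either, with limma adjusted p-values from 0.0509 to 0.0709.

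The hard keratin list was lower in both strata that hold the 2 groups, with a median of -0.95 in stratum 1, which has 1 library per group, and -1.10 in stratum 2. Single genes of the class fell less in stratum 1: the differences in strata 1 and 2 were -0.45 and -1.40 for Krtap4-2, -0.61 and -1.48 for Krtap1-3, -0.66 and -1.39 for Krtap9-3, -0.66 and -1.35 for Krtap1-4, and -0.53 and -0.93 for Krt39. The mean log2 score of the list was 10.17 ± 0.15 (SD, n = 5) in controls and 9.26 ± 0.33 (SD, n = 4) in transgene libraries, a 0.532-fold level, and all 4 transgene libraries lay below all controls. The exact permutation test of the score gave p = 0.00794, the smallest possible, and 0.127 after adjustment over 16 cell type scores; within strata p was 0.05, again the smallest possible. Camera gave the list an adjusted p of 8.32e-12 with the preset correlation and an adjusted p of 0.48 with an estimated correlation, since its members vary together between libraries.

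Of the 12 largest falls among called genes with a standard symbol, 11 were hard keratin or keratin-associated protein genes, and they ran from -1.25 for Krtap3-1 to -1.10 for Krt31. With stratum terms, Krtap13 (-1.21), Krtap9-3 (-1.18), Krtap13-1 (-1.17), Krt34 (-1.16) and Krt81 (-1.14) passed. Krtap1-3 (-1.22), Krtap1-4 (-1.14) and Krtap4-2 (-1.12) did not pass, with adjusted p-values of 0.0651, 0.0581 and 0.0617. All 20 tested keratin-associated protein genes were lower in the group-only fit, and 7 of them were lower with stratum terms. The remaining gene of the 12 was Alb, encoding serum albumin, which fell by 1.13 (adjusted p 0.0221 with stratum terms) and was lower in every transgene library than in every control.

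Genes of the cornified envelope, the protein shell of the outermost keratinocytes, were lower by less. Of 25 tested members 10 fell (11 when adjusted over the list alone), and 1 fell with stratum terms (6 when adjusted over the list alone). The one member was the small proline-rich protein gene Sprr2b, at -0.58 (adjusted p 0.0418). Sprr1b (-0.38), Lce3c (-0.31) and Sprr2i (-0.26) passed in the group-only fit alone. The list median was -0.17 (camera adjusted p 0.00303; adjusted p 0.799 with an estimated correlation), at -0.27 in stratum 1 and -0.12 in stratum 2, and the list did not pass in stratum 2 alone (adjusted p 0.146). Once the length trend was taken out, 1 member was lower (1 when adjusted over the list alone), the median was -0.04 and the camera adjusted p was 0.562, and without transgene replicate 2 the median was -0.10 (adjusted p 0.0169).

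Of 20 tested stress and wound keratinocyte genes 5 fell (5 when adjusted over the list alone), including the antimicrobial peptide gene Defb4 at -0.41, the protease inhibitor gene Slpi at -0.32, the cytokine gene Il1f6 at -0.30 and Stfa3 at -0.21. Defb4 alone passed with stratum terms (adjusted p 0.0263; 4 members when adjusted over the list alone). The list median was -0.08 (camera adjusted p 0.0057; adjusted p 0.799 with an estimated correlation), and it was -0.13 without transgene replicate 3. It was -0.23 in the 1 pair of libraries of stratum 1 and -0.06 in stratum 2, and the list did not pass in stratum 2 alone (adjusted p 0.0725). The median turned to 0.04 with the length trend taken out, and 7 members were higher and 1, Defb4, lower (7 and 3 when adjusted over the list alone).

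The other keratinocyte layers did not move with the hard keratins. Basal keratinocyte genes had a median of 0.01 and a mean of -0.00 over 20 members, with 2 higher and 4 lower (2 and 5 when adjusted over the list alone; camera adjusted p 0.82) and with 1 lower in the fit with stratum terms (1 higher and 4 lower when adjusted over the list alone). The basal keratins Krt5 (-0.10, adjusted p 0.282) and Krt14 (-0.16, adjusted p 0.0536) did not pass, although Krt14 did without control replicate 2 (-0.18, adjusted p 0.0484) or transgene replicate 4 (-0.20, adjusted p 0.026). Suprabasal oral keratinocyte genes had a median of -0.07 over 25 members, with 1 higher and 4 lower (1 and 4 when adjusted over the list alone; camera adjusted p 0.535) and with 1 lower in the fit with stratum terms (1 when adjusted over the list alone). The oral keratins Krt13 (-0.13, adjusted p 0.406) and Krt4 (0.01, adjusted p 0.95) did not pass, and Krt4 turned to -0.05 without control replicate 2, -0.04 without transgene replicate 3 and -0.07 without transgene replicate 4. In stratum 1 alone, the pair of libraries differed by -0.26 in the basal median and by -0.33 in the suprabasal median, against 0.10 and 0.05 in stratum 2.

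Ribosomal protein genes were lower by a small and even amount. All 26 tested members fell in the group-only fit (26 when adjusted over the list alone), and 14 fell with stratum terms (26 when adjusted over the list alone). The median was -0.29 (camera adjusted p 9.37e-19; adjusted p 0.48 with an estimated correlation). Rpl19 changed by -0.34, Rpl13 by -0.32, Rpl18 by -0.28 and Rpl3 by -0.27, each past the test with stratum terms. The median was -0.14 in stratum 1 and -0.38 in stratum 2. These transcripts are short, with a median length of 963 bases against 3141 for all tested genes, and with the length trend taken out the median was -0.17 with 23 members lower (25 when adjusted over the list alone). With stratum terms as well limma called 0, against 24 lower at an unadjusted p under 0.05.

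Of 23 tested oxidative stress response genes, 11 fell and 1 rose (15 and 1 when adjusted over the list alone), and 4 fell with stratum terms (10 when adjusted over the list alone). The metal-binding metallothionein genes Mt2 (-0.40) and Mt1 (-0.33), the glutathione transferase gene Gsta3 (-0.31) and the carbonyl reductase gene Cbr3 (-0.29) were those 4. The list median was -0.17 (camera adjusted p 0.000213; adjusted p 0.16 with an estimated correlation), with -0.19 in stratum 1 and -0.15 in stratum 2. With the length trend taken out the median was -0.04 with 5 members lower (6 when adjusted over the list alone), and Mt2 was not called (-0.18, adjusted p 0.0545).

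Among cell cycle genes, 8 of 36 tested members fell (8 when adjusted over the list alone). The mitotic kinase genes Cdk1 (-0.26) and Aurkb (-0.23), the thymidylate synthase gene Tyms (-0.19) and the replication clamp gene Pcna (-0.17) were among them. With stratum terms limma called 0 over all genes, 6 when adjusted over the list alone and 8 at an unadjusted p under 0.05. The median was -0.13 (camera adjusted p 2.08e-05; adjusted p 0.48 with an estimated correlation), with -0.24 in stratum 1 and -0.09 in stratum 2. Taking out the length trend left 7 members lower (8 when adjusted over the list alone), and Pcna was not called (-0.08, adjusted p 0.125).

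Of 37 oxidative phosphorylation genes 13 fell (19 when adjusted over the list alone), including Cox8b (-0.25), Cox5a (-0.21), Uqcrb (-0.19) and Ndufv2 (-0.19), which encode subunits of the respiratory chain. The fit of limma with stratum terms called 0, against 15 lower at an unadjusted p under 0.05. The median was -0.16 (camera adjusted p 9.5e-07; adjusted p 0.799 with an estimated correlation). It was 0.06 in stratum 1 and -0.25 in stratum 2, and with the length trend taken out it was -0.00 with 0 members called by limma, against 3 lower at an unadjusted p under 0.05.

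Extracellular matrix and vessel genes were higher, and mainly in stratum 2. Of 25 fibroblast and matrix genes 13 rose (17 when adjusted over the list alone), with a median of 0.28 (camera adjusted p 2.08e-05; adjusted p 0.799 with an estimated correlation). The fibrillin gene Fbn1 differed by 0.61, Col6a3 by 0.50, Lox by 0.24 and Postn by 0.23. With stratum terms limma called 0, against 14 higher at an unadjusted p under 0.05. The list median was -0.00 in stratum 1 and 0.39 in stratum 2. Fbn1 differed by -0.06 in stratum 1 and 0.89 in stratum 2, whereas Postn differed by 0.22 and 0.23. The list's median transcript length is 4741 bases. With the length trend taken out the median was 0.20 and 2 members were higher (2 when adjusted over the list alone), while Fbn1 (0.44, adjusted p 0.0685) and Lox (0.18, adjusted p 0.0576) were not called.

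The 12 largest rises in the group-only fit were led by Bmi1, followed by Nrip3 at 0.66 and Fbn1 at 0.61. The others included Col4a2 at 0.58, Col4a1 at 0.58, Hspg2 at 0.53 and Col15a1 at 0.49, beside the matrix genes Col1a1 at 0.57 and Tnc at 0.50 and the apelin receptor gene Aplnr at 0.49. Peg3, an imprinted zinc finger gene, was higher by 0.51 and was the only one of the 12 called with stratum terms (adjusted p 0.0418). Peg3 differed by 0.48 in stratum 1 and 0.53 in stratum 2, while Col4a1 and Col4a2 each differed by -0.04 in stratum 1. Without the length trend Fbn1, Col4a1, Col4a2, Col1a1, Tnc, Hspg2, Col15a1 and Aplnr were not called, with differences from 0.34 for Hspg2 to 0.48 for Col4a2 and adjusted p-values from 0.0532 for Hspg2 to 0.107 for Col4a1. Several calls also ended with 1 library left out. Col4a1, Col4a2 and Tnc were not called without control replicate 2, 3, 4 or 5 or without transgene replicate 3 or 4, and their lowest values were 0.39, 0.42 and 0.38, without transgene replicate 3. Nrip3 was not called without control replicate 2, 3, 4 or 5 or transgene replicate 4 (lowest 0.64), Col1a1 without control replicate 3, 4 or 5 or transgene replicate 3 or 4 (lowest 0.44), Aplnr without control replicate 4 or 5 or transgene replicate 3 or 4 (lowest 0.45), and Col15a1 without control replicate 5 or transgene replicate 4 (lowest 0.47).

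Of 15 endothelial genes 6 rose (6 when adjusted over the list alone), including the VEGF receptor genes Kdr (0.39) and Flt1 (0.24), Robo4 (0.25) and Eng (0.23). With stratum terms limma called 0 over all genes, 6 when adjusted over the list alone and 6 higher at an unadjusted p under 0.05. The median was 0.19 (camera adjusted p 0.0057; adjusted p 0.799 with an estimated correlation), with 0.01 in stratum 1 and 0.26 in stratum 2, and it was 0.11 (adjusted p 0.0607) without transgene replicate 3. Of 14 lymphatic, smooth muscle and pericyte genes 5 rose (7 when adjusted over the list alone), with Pdgfrb at 0.34, Cspg4 at 0.26, Smtn at 0.15 and Prox1 at 0.14. Their median was 0.13 (camera adjusted p 0.042; adjusted p 0.799 with an estimated correlation), at -0.06 in stratum 1 and 0.16 in stratum 2. With stratum terms limma called 0 of them, against 6 higher at an unadjusted p under 0.05. This list did not pass without control replicate 3 or 4 or transgene replicate 2, 3 or 4 (lowest median 0.11, adjusted p 0.109, without control replicate 3). Flt1 was not called without control replicate 3 or 5 or transgene replicate 2 or 3 (lowest 0.21), Cspg4 without control replicate 2, 3, 4 or 5 or transgene replicate 2, 3 or 4 (lowest 0.21), and Prox1 without control replicate 3, 4 or 5 or transgene replicate 2 or 4 (lowest 0.11).

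With the length trend taken out, 2 of the 15 endothelial genes were higher (4 when adjusted over the list alone) at a list median of 0.15 (camera adjusted p 0.00164; adjusted p 0.601 with an estimated correlation), and Kdr (0.30, adjusted p 0.0583) and Flt1 (0.13, adjusted p 0.118) were not called. Of the 14 lymphatic, smooth muscle and pericyte genes 2 were higher (2 when adjusted over the list alone) at a median of 0.09 (camera adjusted p 0.051; adjusted p 0.601 with an estimated correlation), and Cspg4 (0.13, adjusted p 0.165) and Prox1 (0.01, adjusted p 0.872) were not called.

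Several macrophage genes were higher in both strata. Of 23 macrophage and dendritic cell genes 7 rose (7 when adjusted over the list alone) and 2 rose with stratum terms (5 when adjusted over the list alone). These 2 were the scavenger receptor gene Cd163 (0.47, adjusted p 0.0407) and the colony stimulating factor receptor gene Csf1r (0.27, adjusted p 0.0418). Csf1r differed by 0.25 in stratum 1 and 0.28 in stratum 2, and Cd163 by 0.23 and 0.57. The mannose receptor gene Mrc1 (0.35) and the integrin gene Itgam (0.26) passed in the group-only fit alone. The list median was 0.05 (camera adjusted p 0.0417; adjusted p 0.799 with an estimated correlation) and 0.04 in each of stratum 1 and stratum 2, and the list did not pass in stratum 2 alone (adjusted p 0.13). Without transgene replicate 3 it was 0.017 (adjusted p 0.237), and without control replicate 3 it was 0.029 (adjusted p 0.109). Nor did the list pass without control replicate 1 (0.044, adjusted p 0.0567), control replicate 4 (0.034, adjusted p 0.0509) or transgene replicate 1 (0.042, adjusted p 0.0571). The list median was 0.12 with the length trend taken out, and 8 members were higher (13 when adjusted over the list alone).

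**Figure D2:**
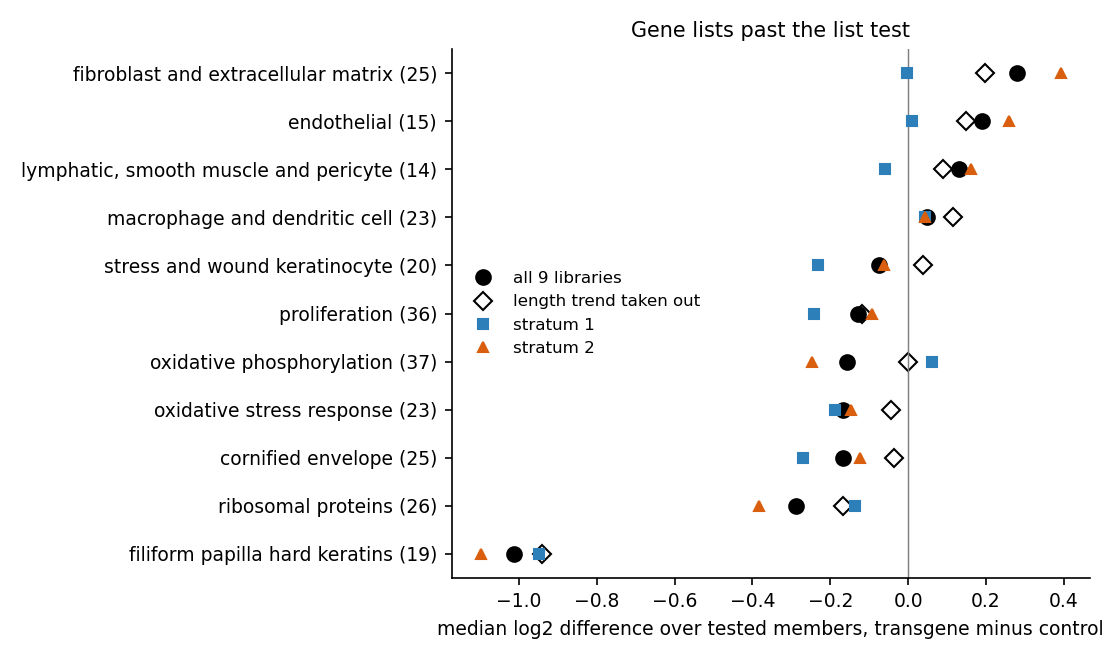
Median log2 difference (transgene minus control) over tested members of the 11 gene lists past the list test, with the number of tested members in brackets. Black circles are all 9 libraries, open diamonds the values with the length trend taken out, blue squares stratum 1 and orange triangles stratum 2; the hard keratin list lies at -0.94 or lower in each of the 4, whereas the matrix list lies at -0.00 in stratum 1.

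Skeletal muscle, the bulk of the tongue, showed no common shift. Of 28 fast muscle genes 6 rose and 2 fell in the group-only fit (6 and 2 when adjusted over the list alone), with a median of -0.04, a mean of 0.01 and a camera adjusted p of 0.929. Limma called 0 with stratum terms, against 4 higher and 2 lower at an unadjusted p under 0.05, and with the length trend taken out 1 was higher. The fast myosin gene Myh4 differed by 0.23 (adjusted p 0.0424; 0.25 with stratum terms) and the calcium pump gene Atp2a1 by 0.11 (adjusted p 0.194). Myh4 was not called without control replicate 2, 3, 4 or 5 or transgene replicate 2, 3 or 4 (lowest 0.19), or with the length trend taken out (0.14, adjusted p 0.171). Among 34 Polycomb subunits 4 rose and 2 fell (4 and 2 when adjusted over the list alone), with a median of -0.03, a mean of 0.07 that includes Bmi1 and a camera adjusted p of 0.929. Limma with stratum terms called 0 of the subunits, against 4 higher and 2 lower at an unadjusted p under 0.05 and 2 higher when adjusted over the list alone. Rbbp4 fell by 0.13 (adjusted p 0.00714; 0.112 with stratum terms) and Rbbp7 differed by -0.08 (adjusted p 0.0568). Of 14 kinase inhibitor and senescence genes 2 fell (2 when adjusted over the list alone), with a median of -0.02 (camera adjusted p 0.535). None (0) passed in limma with stratum terms, against 2 lower at an unadjusted p under 0.05 and 1 lower when adjusted over the list alone. In that list Igfbp5 differed by 0.12 (adjusted p 0.0538) and Cdkn1a, which encodes p21, by -0.16 (adjusted p 0.0771). Without transgene replicate 4 both passed, Igfbp5 at 0.15 (adjusted p 0.0327) and Cdkn1a at -0.21 (adjusted p 0.029), and without control replicate 2 Igfbp5 passed at 0.14 (adjusted p 0.0451).

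Over all 14490 tested genes, the group-only fit called 1690 genes higher and 1847 lower, and the fit with stratum terms called 74 higher and 166 lower, all of them among the first. At an unadjusted p under 0.05 the fits held 5647 and 3336 genes. With the length trend taken out limma called 900 higher and 986 lower, and 6 and 4 with stratum terms as well. Of the former 1153, and of the latter 7, were also called in the group-only fit. Neither set is thus a subset of its calls. Long transcripts made up most of the higher calls and short ones most of the lower: the median length was 5733 bases for higher and 1628 for lower genes in the group-only fit, and 6547 and 1062 with stratum terms. Across genes, which are not independent replicates, the log2 difference correlated with log2 length at Pearson r = 0.581 (Spearman rho 0.619). Within stratum 1 r was 0.117 and within stratum 2 it was 0.616. With genes cut into 10 equal parts by length, the median difference went from -0.13 in the shortest part to 0.14 in the longest.

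**Figure D3:**
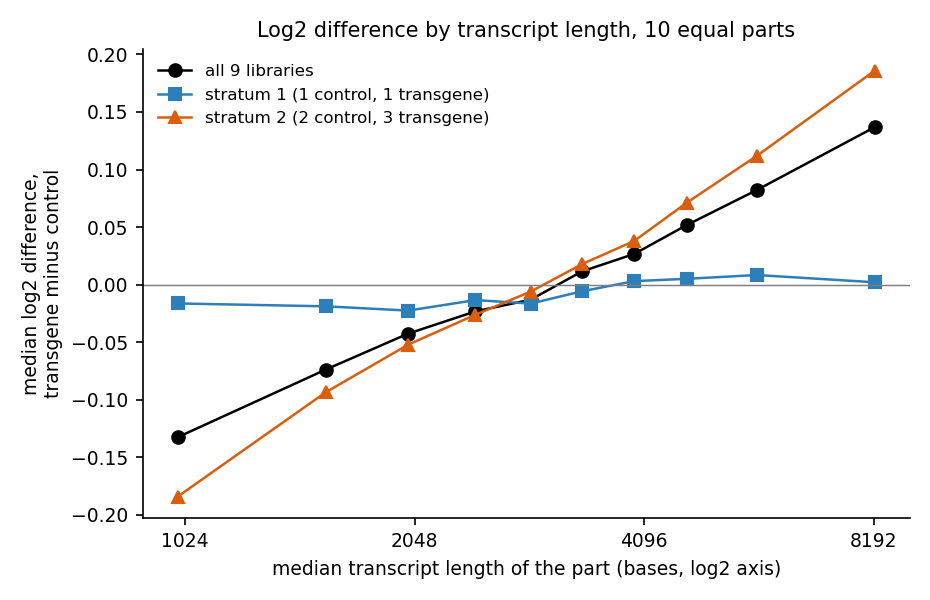
Median log2 difference (transgene minus control) of tested genes in 10 equal parts by transcript length (bases, log2 axis), for all 9 libraries (black), stratum 1 (blue) and stratum 2 (orange). In stratum 2 the medians run from -0.18 to 0.19 and in stratum 1 from -0.02 to 0.00.

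The authors' deposited table holds 429 genes with a positive and 552 with a negative log2 fold change. Its largest values were the Y-linked genes Kdm5d (0.66) and Ddx3y (0.56) with Gucy1a2 (0.57), Peg3 (0.57) and Sned1 (0.56), and its smallest were Krtap3-3 (-1.13), Krt39 (-0.74), Prr9 (-0.71), Krtap9-3 (-0.70) and 2310061N02Rik (-0.69). Of the 981 genes, 980 had the same direction in the group-only fit, 973 were called by it and 216 were called with stratum terms. The exception in direction was the Y-linked gene Eif2s3y, at 0.32 in the authors' deposited table and -0.03 in the deposited log2 values, named after its value was seen. Pearson r of the log2 differences across genes was 0.946, and since both come from the same libraries it is no independent check. In the log2 values Kdm5d differed by 0.17 (adjusted p 0.0489; 0.212 with stratum terms), Ddx3y by 0.18 (adjusted p 0.00793; 0.104 with stratum terms), Gucy1a2 by 0.41 (adjusted p 0.00102; 0.0407 with stratum terms) and Sned1 by 0.47 (adjusted p 0.00436; 0.0565 with stratum terms). Krt39 at -0.81, Prr9 at -0.72 and 2310061N02Rik at -1.25 were lower in both fits. The size of the fall was close to the authors' for Krtap3-3, Krt39 and Prr9. It was larger in the log2 values for Krtap9-3 (-1.18 against -0.70) and 2310061N02Rik (-1.25 against -0.69). Krtap3-1, Krtap13, Krt34, Krt81, Krt31 and Krt85, at -1.25 to -1.08 in the log2 values, are not among the authors' 5 smallest. None of them lies below Chia (-0.63), named outside the rule, in the authors' table. Each is therefore either absent from it or above that value. Kdm5d was not called without control replicate 2, 3, 4 or 5 or transgene replicate 2 or 4 (lowest 0.13), or with the length trend taken out (0.04, adjusted p 0.552).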

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

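Transgene replicate 4 stood apart in 3 genes: Igfbp5 was at 15.36 against 15.46 in each of the other 3 transgene libraries, Rbbp4 was at 11.54 against 11.61 to 11.62, and Sprr1b was at 11.95 against 11.56 to 11.60. Transgene replicate 3 stood apart in 2 scores, the neutrophil and mast cell score at 7.47 against 7.64 to 7.66 and the glycolysis score at 13.43 against 13.25 to 13.28. These 5 came from 246 groups of 4 or 5 values examined. No rate expected by chance is given, since the cleared strata tie the values of libraries to each other. Bmi1 at 14.87 in transgene replicate 3 lay far from the other 3 but not far enough to meet the same limit.

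Of the tests in this part, those of the transgene as the source of the length trend, of the epithelial share, of close gene copies and of the earlier correction were chosen after the result was seen. Long genes were higher and short genes lower in the transgene libraries. If the libraries differed in how well long transcripts were captured, genes within 1 cell type or process should follow length as all genes do. Within 37 fixed lists the slope of the log2 difference was 0.0874 per doubling of length (95% interval 0.0709 to 0.104 from resampled lists) against 0.0879 over all genes, which is consistent with length-dependent yield. The slope in stratum 1 was 0.176 of that in stratum 2, but stratum 1 holds 1 library per group, so an effect of the Bmi1 transgene itself cannot be told apart from the libraries' yield.

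Hard keratin and keratin-associated protein genes were lower in transgene libraries. Length-dependent yield is argued against as the whole cause, since with the length trend taken out the median over the 18 members with a known length was -0.94 with 16 lower, against -1.01 for the same members before. A lower share of epithelium would lower the basal and suprabasal keratinocyte genes as well, and their joint median was -0.019 with the middle 50% of members between -0.13 and 0.09. In the 1 pair of libraries of stratum 1 the basal and suprabasal medians were -0.26 and -0.33, beside -0.95 for the hard keratins. In stratum 2 they were 0.10 and 0.05, beside -1.10. The joint median thus does not describe stratum 1 by itself. The keratins, whose median with Hoxc13 was -0.91, do not settle whether reads were shared between close copies, since several are close relatives themselves. Hoxc13, which is no keratin, changed by -0.52 (limma adjusted p 0.0709 with stratum terms), and 1 gene cannot decide the question. A lower expression of the filiform papilla program in transgene tongues may account for the fall, as a hypothesis found and tested on the same libraries, and an uneven recovery of the horny surface layer from the whole tongues was not tested and stays open.

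The number of genes called in the group-only fit was 3537, and it was 240 with terms for the strata, although the log2 differences were identical. Since no stratum effect is left in any gene, both fits leave the same residuals. They differ in the residual degrees of freedom, 7 and 5, and in the SE. The SE is also larger with stratum terms because the groups are spread unevenly over the strata. For Krt31 it was 0.165 in the group-only fit and 0.201 with stratum terms. A correction of the values before deposit is a candidate explanation for the 2 empty directions of the 7 that the group-only fit counts as present.

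For the numbers of genes, the splits that treat the real groups like any other are those within strata, and these are too few for a share under 0.05: of 20, the real split gave 74 genes higher and 166 lower with stratum terms, and the highest of the other 19 gave 26 and 1. Of 100 splits drawn from all 126, 1 split (the real one) reached 1690 genes higher, with 931 in the highest other, and 1 split (the real one) reached 1847 lower, with 912 in the highest other. In the deposited values the strata are cleared of everything except the real groups' contrast, so the real split was favoured in that draw and its share decides nothing, although it meets the limit set beforehand. Chance cannot be excluded for the numbers of gene lists: 72 of 100 splits gave at least 4 lists higher, with 18 in the highest other, and 34 of 100 gave at least 7 lower, with 18 in the highest other. Within strata, 14 of 20 splits gave at least 4 lists higher, with 19 in the highest other, and 8 of 20 gave at least 7 lower, with 17. Why some splits call several times the real number of lists was not tested.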

How the results depend on the processing

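Terms for the strata, stratum 2 alone, the length trend and the Y-linked covariate were chosen after seeing the data; the remaining settings were fixed beforehand. The 1690 higher and 1847 lower genes became 74 and 166 with stratum terms, 333 and 400 in stratum 2 alone, 900 and 986 with the length trend taken out, 6 and 4 with both, and 173 and 276 with the Y-linked covariate. Genes also called in the group-only fit numbered 1153 with the length trend taken out and 7 with both. They numbered 652 in stratum 2 alone and 357 with the Y-linked covariate. The unadjusted p was under 0.05 for 2271 genes with both and 3846 in stratum 2 alone. The Y-linked covariate ran from 8.055 to 8.169 in transgene libraries and from 7.958 to 8.040 in controls. Since it separates the groups fully, it takes up part of their difference, and its counts do not show an effect of sex. Leaving out 1 library gave 986 (without control replicate 5) to 1698 higher and 1272 to 1828 lower; without control replicate 4 or transgene replicate 2 there were 1057 and 1056 higher. The muscle to keratinocyte covariate gave 2524 and 2765. Other planned settings stayed within 1.5 times. The Bmi1 log2 difference stayed above 0, at 2.44 with stratum terms (adjusted p 0.0672), 2.73 in stratum 2 alone (0.0882) and 2.42 with both corrections (0.116), and ranged from 1.77 to 2.74 with 1 library left out.

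Lists numbered 4 higher and 7 lower. With an estimated correlation camera called 0 and 0, fry called 0 and 4, fry with stratum terms called 0 and 2 (hard keratins at an adjusted p of 0.105 and proliferation at 0.161 no longer passed), and 7 were higher with length and stratum corrections. Those corrections ended the camera calls of oxidative phosphorylation (adjusted p 0.759), cornified envelope (0.557) and stress and wound keratinocyte (0.141) as lower. The Wnt list passed as lower there (0.0135). With 1 library left out 2 to 5 were higher and 7 to 8 lower, with 2 higher without control replicate 4 or transgene replicate 3. Of 16 cell type scores 0 passed the exact permutation test with means (smallest adjusted p 0.127; 5 at an unadjusted p under 0.05), and 3 passed with medians over members (hard keratins, cornified envelope, and neutrophil and mast cell). Of the authors' 981 genes limma called 216 with stratum terms, 571 with the length trend taken out and 4 with both.

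Leaving out 1 library ended between 0 (without control replicate 1 or transgene replicate 1) and 12 (without control replicate 5) calls among the named genes, in 12 genes: Aplnr, Col1a1, Col4a1, Col4a2, Col15a1, Cspg4, Flt1, Kdm5d, Myh4, Nrip3, Prox1 and Tnc.

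Directions turned with the length trend taken out, with and without stratum terms, for Cox8b (0.016), Stfa3 (0.037), Uqcrb (0.026) and the list stress and wound keratinocyte (0.038). They turned in stratum 2 alone for Krt13 (0.047) and Krt5 (0.018) and with library weights for Krt4 (-0.081). With the Y-linked covariate Krt4 (-0.14) and Kdm5d (-0.038) turned, but Kdm5d is itself part of that covariate. With 1 library left out Krt4 ranged from -0.066 to 0.093 and Ccnd1 from -0.046 to 0.030, neither past the test. The cause was not tested. With both corrections the hard keratin list stayed at a median of -0.94 over the 18 members with a known length, with 0 called by limma and 16 lower at an unadjusted p under 0.05; Krtap3-3 changed from -1.13 (SE 0.13) to -0.96 (SE 0.13, adjusted p 0.0504). The fold was smaller at the same spread, and fewer genes passed with it (10 against 240), which also enters its adjusted p; these parts were not separated. The planned covariate from Y-linked genes and Xist was not run because Xist was not analysed here, and the authors' unadjusted threshold was not run because their table holds genes past the adjusted one. No paired analysis was possible because the labels give no replicate numbers shared between groups. Read depth is unknown, so its limits cannot be stated.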

Other observations

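In the group-only fit the following cell type lists did not pass the list test. Taste bud genes had a median of -0.03 over 16 members, with 0 called by limma and 0 at an unadjusted p under 0.05. Salivary gland genes had a median of -0.00 over 19 members with 2 higher, T and NK cell genes -0.02 over 9 members with 1 lower, and slow and cardiac type muscle genes -0.05 over 11 members with 2 higher. The neutrophil and mast cell list had a median of 0.08 over 11 members with 2 higher, the adipocyte list 0.04 over 12 with 2 higher, and the Schwann cell and nerve list 0.10 over 15 with 3 higher, at -0.16 in stratum 1 and 0.18 in stratum 2. The muscle regeneration list had a median of 0.01 over 17 members with 2 higher and 1 lower. With the length trend taken out, camera put the adipocyte list (median 0.10, adjusted p 7.69e-05, 4 members higher) and the neutrophil and mast cell list (median 0.15, adjusted p 0.00733, 1 member higher) past the test as higher; with an estimated correlation as well, each had an adjusted p of 0.299.

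Of 21 Wnt pathway target genes 5 fell and 1 rose, with a median of -0.05 (camera adjusted p 0.216). Wnt4 changed by -0.23 (adjusted p 0.00564; 0.0744 with stratum terms) and differed by -0.23 in stratum 1 and -0.22 in stratum 2, while Ccnd1, the cyclin D1 gene, differed by -0.02 (adjusted p 0.818) and turned to 0.01 without control replicate 3 and 0.03 without transgene replicate 4. Stem and progenitor markers had a median of -0.00 over 18 members, including Bmi1, with 4 higher and 1 lower, and developmental transcription factors -0.04 over 41 with 1 higher and 5 lower. The Notch list had 4 higher and 1 lower of 15 (median 0.09), the Hedgehog list 1 higher and 2 lower of 12 (0.08), the epithelial mesenchymal transition list 4 higher of 19 (0.03), the interferon list 1 higher of 28 (0.03), the inflammatory cytokine list 1 lower of 15 (0.02) and the immediate early list 3 lower of 24 (0.00). The heat shock list had 1 higher and 3 lower of 21 (-0.01), the glycolysis list 1 and 1 of 20 (0.00), the lipid metabolism list 5 and 1 of 24 (0.02), the retinoid list 4 and 2 of 17 (0.01) and the circadian list 0 called by limma of 17 (-0.01), against 2 higher and 1 lower at an unadjusted p under 0.05. Adjusted over the list alone, the numbers in these paragraphs differ for neutrophil and mast cells (3 higher), Schwann cells (0), salivary gland (1 higher), developmental factors (4 lower), Hedgehog (5 higher), lipid metabolism (2 lower), retinoids (4 lower) and immediate early genes (2 lower).

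With stratum terms limma called 1 gene lower in each of the Wnt, stem and progenitor, developmental, heat shock and immediate early lists and 1 gene higher in each of the epithelial mesenchymal transition and glycolysis lists. Lists share members, such as Myc in the Wnt, stem and progenitor and immediate early lists, so these calls need not be separate genes. In the remaining 15 lists of this part it called 0, against 26 higher and 10 lower at an unadjusted p under 0.05, summed over the lists. With the length trend taken out, camera put the inflammatory cytokine list past the test as higher (median 0.06, adjusted p 0.00313, 6 members higher and 0 called lower, with 1 lower at an unadjusted p under 0.05) and the Wnt list past it as lower (median -0.06, adjusted p 0.02, 4 members lower). With an estimated correlation as well, their adjusted p-values were 0.341 and 0.518. In stratum 2 alone camera put the Schwann cell and nerve (adjusted p 0.00442), epithelial mesenchymal transition (0.0324) and lipid metabolism (0.00961) lists past the test as higher, with medians of -0.16, -0.11 and -0.14 in stratum 1; with an estimated correlation in stratum 2 alone each had an adjusted p of 0.787.

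In 9 genes of the authors' deposited table the mean of the deposited log2 values lay more than 0.9 below the log2 of the authors' mean signal, against a median gap of -0.03 over all 981. They were the Y-linked genes Ddx3y (-1.54), Eif2s3y (-1.37), Kdm5d (-0.99) and Uty (-0.96) and the gland or secreted product genes Muc5b (-3.14), Tff2 (-2.56), Prb1 (-2.06), Chia (-1.44) and Prpmp5 (-1.40), chosen after their values were seen. In the deposited log2 values the Y-linked genes spanned 0.37 for Kdm5d, 0.29 for Ddx3y, 0.22 for Uty and 0.20 for Eif2s3y over the 9 libraries. The deposited values hold no differences between strata beyond the group means, so these small spans do not show that all mice were of 1 sex. An additive correction per stratum would keep differences within a stratum. If such a correction was made, the small spans argue against a mix of both sexes within any stratum. Whether sex differed between strata, and whether it underlies the gaps of the Y-linked genes, was not tested. The sex of the mice is not given in the labels.

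Per library, the slope of log2 value on log2 length, relative to the mean of all libraries, was -0.01 per doubling in control replicate 1 and 0.02 in transgene replicate 1, the 2 libraries of stratum 1. It was -0.07 and -0.04 in control replicates 2 and 3, against 0.06, 0.05 and 0.07 in transgene replicates 2, 3 and 4. Control replicates 4 and 5 were both at -0.04. In every tested gene the mean of these 2 libraries equals the control mean, because stratum 3 holds no transgene library. Their slopes are therefore no separate check on the trend. The sum of the 2 slopes in stratum 1 is likewise tied to the group means.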
